A study of Mus musculus with 7 samples.

How the data were processed

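Whole-genome bisulphite libraries were made from sorted mouse PGCs, each from DNA of 10000 cells per the labels' protocols, with methylated adaptors, bisulphite conversion after adaptor ligation and 16 PCR cycles, and sequenced on Illumina HiSeq instruments. Unmethylated lambda phage DNA was added in some cases per the labels' protocols, and its conversion rate was not used here.

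The authors deposited one table per group, holding for each CpG a methylation level as a fraction from 0 to 1. Per the submitters' processing notes, reads were handled with Trim Galore 0.3.1 and Bismark 0.13.0, a trimmer and a bisulphite aligner and caller, on the mm9 genome. The names of the deposited tables, given in the labels, describe symmetric CpGs at 8x, taken here as both strands joined and a minimum of 8 reads. Removal of duplicate reads and how the libraries of a group were pooled are not given in the sources used here. The tables hold no methylated or total read counts, so depth is unknown and no interval on reads could be given. A level of 0 at a CpG read 8 times is compatible with a sizeable true level, so statements rest on windows and means rather than on single CpGs. Over a fixed set of CpGs the mean level is not expected to shift with depth, but the count of CpGs past a threshold is. Depth also decides which CpGs reach the minimum of 8 reads, and so which CpGs enter a mean.

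Samples were grouped by title: E10.5 (1 library), E11.5 (2), E12.5 female (2) and E12.5 male (2). The sex characteristic reads female for both male libraries and is filled for 1 of the 2 female libraries, so the titles were used, and the number of X and Y CpGs was checked against them.

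The design, alternatives, gene lists and rule for named windows were fixed before the data were examined. That design foresaw Fisher's exact tests on read counts where counts were given, and the size of the difference alone where they were not, which applied here. It also foresaw promoters and gene lists where an annotation of the files' build was given. The gene table used here is on GRCm38, whose coordinates differ from mm9, so promoters and lists of germline, imprinted, pluripotency, somatic and other genes were not analysed, and windows are named by coordinate. Coordinates are given as 1-based, on the assumption that the tables follow the BED convention of starts counted from 0, which was not checked against the mm9 sequence.

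Levels were converted from fractions to percent and joined by position with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The main set was the 8916125 nuclear CpGs present in all 4 tables. Levels are unweighted means over CpGs, with the SD over the 19 autosomes. Differences between groups were tested with an exact two-sided sign-flip test over the 19 autosome means, which measures agreement between chromosomes and not between animals. All 4 contrasts were tested, and each p was the smallest possible, so that Benjamini-Hochberg adjustment leaves the values as they are. Local CpG density was the number of other CpGs of any table within 100 bp on either side, in 4 classes. Windows were non-overlapping, 2 kb long and held at least 5 common CpGs, and their level was the mean over CpGs. A window or CpG was counted where the groups differed by at least 20 percentage points, and a window was called residual at 20% or more in both E12.5 groups. The named windows were the 5 largest falls and 5 largest rises per contrast and the 10 highest at E12.5, of which the text gives a part.

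The window calls were tested on simulated data with the real CpG positions of chromosome 19 (17672 windows), 8 reads per CpG and 200 windows changed by 30 points. For the E11.5 against E10.5 simulation 96.0% of changed windows were recovered and 0.641% of unchanged windows called. For E12.5 females against E11.5 these were 95.5% and 0.137%, for E12.5 males against E11.5 94.0% and 0.126%, and for females against males 96.5% and 0.0572%. The simulation treats CpGs as independent. Both simulated groups start from the level of the earlier group (males in the comparison of the sexes), and 8 reads is the minimum depth. The simulated rates are therefore not those at the real depth and levels.

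Alternatives were every CpG of each table, autosomes only, thresholds of 10 and 30 points or percent, windows of 1 kb and 5 kb, at least 10 CpGs per window, and density within 250 bp. Subtraction of the mitochondrial level, CpGs common to the E11.5 and E12.5 groups alone, and CpGs outside residual windows were chosen after seeing the data. Higher coverage minimums, coverage weighting, a coverage maximum and thinning of reads need read counts and were not run. Figures were drawn with matplotlib 3.10.9, and Wilson intervals were computed with scipy 1.17.1.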

Results

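Whole-genome bisulphite sequencing was used to measure CpG methylation in mouse primordial germ cells (PGCs), the embryonic precursors of eggs and sperm, at the embryonic stages E10.5, E11.5 and E12.5, named by days of development. In this assay unmethylated cytosines are converted and read as thymine, so that the share of unconverted calls at a CpG gives its methylation level. The method does not separate 5-methylcytosine from 5-hydroxymethylcytosine. PGCs had been sorted from embryos of MF1 crossed with a GOF18ΔPE-EGFP reporter line, a transgene that marks germ cells. The 7 libraries fell into 4 groups: E10.5 with 1 library, and E11.5, E12.5 female and E12.5 male with 2 libraries each. The sexes were kept apart at E12.5, after sex specification had begun. One set of methylation levels was deposited per group, so the spread between libraries of a group could not be measured, and every comparison below is between pooled libraries. Spread is given over the 19 autosomes or over CpGs, which are not biological replicates.

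The E10.5 group held 10266450 CpGs, the E11.5 group 17673951, the E12.5 female group 15641790 and the E12.5 male group 17519340. Of these, 8916125 nuclear CpGs were present in all 4 groups, and levels were compared over them unless another set is named. Read depth per CpG was unknown beyond the minimum of 8 reads named by the submitters. The sex chromosomes separated the E12.5 groups. The male group held 5225 Y CpGs and the female group 231. X CpGs numbered 2.07% of autosomal CpGs in the male group and 3.80% in the female group. This order followed the sample titles, whereas the sex characteristic of both male libraries read female.

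Methylation was already low at E10.5 and fell at each later stage. The mean level was 18.01% at E10.5 (SD over the 19 autosomes 0.811), 8.54% at E11.5 (SD 0.441), 6.26% in E12.5 females (SD 0.314) and 6.94% in E12.5 males (SD 0.330). The X chromosome was above every autosome in each group, at 23.4%, 12.9%, 10.0% and 10.2% in the same order. CpGs at 50% or more made up 3.17% of those measured at E10.5, 0.986% at E11.5, 0.673% in E12.5 females and 0.612% in E12.5 males. Mitochondrial DNA, in which little or no CpG methylation is expected, read 3.37% at E10.5, 3.77% at E11.5, 4.54% in females and 3.82% in males over 222 CpGs. The nuclear level minus this mitochondrial level was 14.6 percentage points at E10.5, 4.77 at E11.5, 1.71 in females and 3.12 in males. At E11.5 and E12.5 the mitochondrial level was above that of the densest autosomal CpGs (in E12.5 females 4.54% against 3.59%), so subtracting it takes off more than unmethylated nuclear sequence read.

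**Figure D1:**
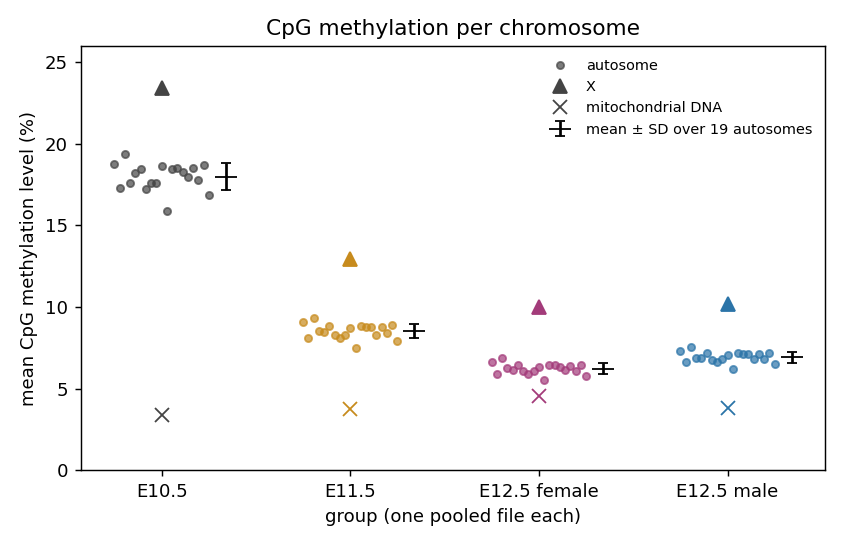
Mean CpG methylation level (%, y axis) per group (x axis) over CpGs present in all 4 groups. Circles are the 19 autosomes, the bar beside them is their mean ± SD, triangles are the X chromosome and crosses are mitochondrial DNA; the X lies above all autosomes in each group, and the mitochondrial level lies between 3.37% and 4.54%.

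The first comparison asked how far methylation was lost between E10.5 and E11.5. Nuclear CpG methylation fell by 9.46 percentage points, to 47.5% of its E10.5 level, or 32.6% after subtraction of each group's mitochondrial level. The loss was seen on 19 of 19 autosomes, with changes from -10.1 to -8.44 points (mean over autosomes -9.48, SD 0.400). Over 2 kb windows with at least 5 common CpGs, 93.5% of 597396 windows were lower at E11.5. The level was lower by at least 20 points in 57957 windows (9.70%) and higher by at least 20 points in 33. Windows with such a loss went from a median of 31.3% to 7.18%. Measured windows 4 kb from them had a median difference of -10.6 points, against -10.2 over all windows. The larger loss thus hardly extended to windows at that distance. These windows were chosen by the difference itself, so windows read high by sampling error at E10.5 would give the same picture. The values do not separate the 2. Of single CpGs, 1924121 (21.6%) were lower by at least 20 points and 78028 (0.875%) were higher.

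The 5 largest losses over windows were changes of -61.1 to -58.9 points. A window on chromosome 16 (82692001 to 82694000, 8 CpGs) went from 86.1% (SD over its CpGs 14.6) to 24.97% (SD 15.9). On chromosome 12 (38392001 to 38394000, 5 CpGs) the level went from 67.2% to 6.11%, and on chromosome 6 (95608001 to 95610000, 6 CpGs) from 69.8% to 9.64%. On chromosome 8 (69574001 to 69576000, 12 CpGs) it went from 85.5% (SD 11.49) to 26.6% (SD 4.99), then to 10.8% in E12.5 females and 3.88% in E12.5 males. The largest gain, on chromosome 12 (105020001 to 105022000, 6 CpGs), was from 33.1% to 72.1%. On chromosome 4 (37930001 to 37932000, 6 CpGs) the level went from 3.52% to 36.5% and back to 0% in females and 2.22% in males. All coordinates are on mm9, and the genes at these windows were not analysed here. These windows are extremes of 597396 and have no replicate value behind them.

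The exact two-sided sign-flip test over the 19 autosomes gave p = 3.8e-06, the smallest it can give, and compares the pooled libraries rather than the stages. In windows simulated on chromosome 19 with no change and 8 reads per CpG, 0.641% differed by 20 points or more, in either direction. Scaled to the 597396 measured windows that rate would be 3829 windows, for counting error alone and not for variation between libraries. Both simulated groups had the E10.5 levels and the minimum of 8 reads, so the rate is not that at the real depth and E11.5 levels. The simulated windows held no fall, whereas the measured windows changed by -10.5 points on average (SD over windows 7.32). The rate therefore does not say how many windows fell by more than the genome as a whole. With at least 10 CpGs per window, 22769 of 317892 windows were lower by 20 points and 0 were higher.

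The level a window had at E10.5 ordered what it held later. Windows at 20% to 30% at E10.5 (183617 windows) had medians of 8.22% at E11.5, 5.42% in E12.5 females and 6.55% in E12.5 males. Windows at 60% to 80% (4725 windows) had medians of 52.9%, 45.6% and 44.5%. Of the windows at 20% to 30%, 0.0953% were at 20% or more in both E12.5 groups, and of those at 60% to 80%, 93.4%. A window that starts near 20% needs a smaller fall to pass below it, so these shares do not compare the size of the loss. Windows between 40% and 60% at E10.5 (18063 windows) lay between these, with 43.7% still at 20% or more in both sexes.

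**Figure D2:**
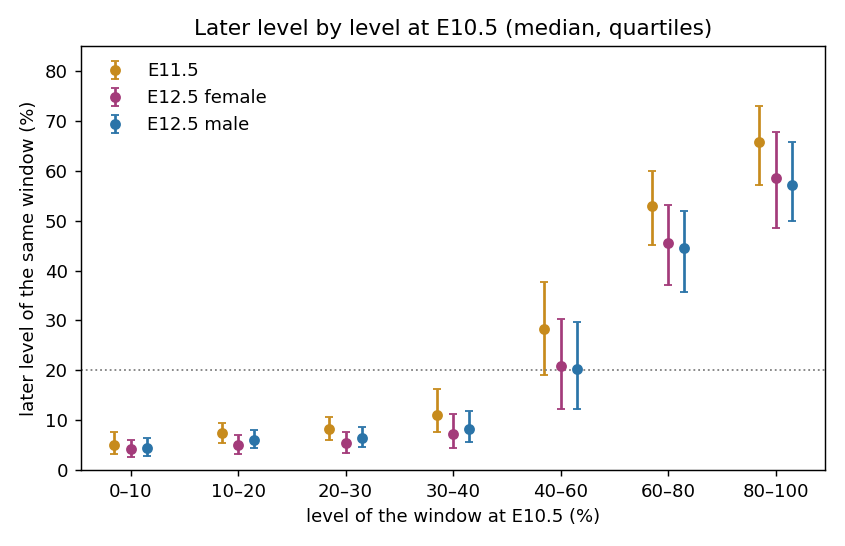
Methylation level of the same 2 kb window at E11.5 and at E12.5 in each sex (%, y axis) by its level at E10.5 (%, x axis). Points are medians over windows and bars run from the lower to the upper quartile; the dotted line marks 20%, and the 3 medians lie between 5.42% and 8.22% in the class of 20% to 30% and between 44.5% and 52.9% in the class of 60% to 80%.

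The next comparisons asked how far each sex at E12.5 lay below E11.5. The E10.5 and E11.5 titles name no sex, so both sexes were measured against the same pooled E11.5 levels. The mean level fell by 2.29 points in females, to 73.2% of E11.5, and fell by 1.60 points in males, to 81.2%. After subtraction of each group's mitochondrial level these shares were 35.9% in females and 65.4% in males, which are low values since the subtraction exceeds the level of the densest nuclear CpGs. Both losses were seen on 19 of 19 autosomes (SD over autosomes 0.136 in females and 0.116 in males). Windows lower by at least 20 points numbered 1606 in females and 1723 in males, against 79 and 54 that were higher. In these windows the median went from 36.5% to 12.47% in females and from 39.5% to 15.04% in males. Measured windows 4 kb from those called lower had a median difference of -3.32 points in females, against -2.42 over all windows. In males these medians were -2.46 and -1.49 points. After subtraction of each group's mitochondrial level, 2023 windows were lower and 57 higher in females, and 1744 lower and 54 higher in males. Which sex had more windows with a loss thus depended on this setting. CpGs lower by at least 20 points, without subtraction, numbered 308502 in females and 272535 in males, against 117120 and 100166 that were higher.

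The largest loss in females, a change of -59.1 points, was on the X (108294001 to 108296000, 5 CpGs), from 80.7% (SD 14.7) to 21.7% (SD 18.98), where males held 44.8%. The largest loss in males, a change of -62.5 points, was on chromosome 17 (16850001 to 16852000, 5 CpGs), from 71.7% (SD 4.56) to 9.17% (SD 9.40), where females held 47.3%. A window on chromosome 2 (149010001 to 149012000, 6 CpGs) was among the 5 largest losses in both sexes, which are measured against the same E11.5 levels, going from 56.2% (SD 17.2) to 12.54% in females and 11.1% in males. Among gains, chromosome 8 (50158001 to 50160000, 5 CpGs) went from 46.4% to 82.5% in females, and chromosome 3 (104642001 to 104644000, 6 CpGs) from 6.76% to 45.2% in males. At E10.5 these 2 windows with gains had stood at 72.3% and 27.4%. The windows with losses had stood at 63.3% on the X, 76.1% on chromosome 17 and 49.0% on chromosome 2. The X and chromosome 2 windows were thus higher at E11.5 than at E10.5. All are extremes of 597396 windows, and no replicate value separates a fall from a high E11.5 reading over few CpGs.

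Both losses of the mean gave p = 3.8e-06 in the exact two-sided sign-flip test over the 19 autosomes, the smallest it can give. The rate of calls in unchanged simulated windows of chromosome 19 at 8 reads per CpG was scaled to all 597396 windows. It would be 821 windows for the female comparison and 752 for the male in both directions together, again for counting error alone. Both simulated groups had the E11.5 levels, again at the minimum depth. The simulated rate too leaves out the fall over all windows, a mean change of -2.59 points in females and -1.76 in males. With at least 10 CpGs, 448 windows were lower and 2 higher in females, and 607 lower and 2 higher in males.

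The sexes were then compared at E12.5. The mean level in females minus that in males was -0.687 points, with 19 of 19 autosomes in that direction (SD over autosomes 0.0389, exact two-sided sign-flip p = 3.8e-06, the smallest it can give). Autosomal CpGs with 0 to 2 neighbours within 100 bp read 6.07% in females (SD 0.125) and 7.03% in males (SD 0.136). CpGs with 16 or more neighbours read 3.59% in females (SD 0.102) and 3.07% in males (SD 0.109), and mitochondrial DNA was higher in females by 0.721 points (SE over CpGs 0.0718). Single CpGs differing by at least 20 points were nearly balanced, with 158785 lower (1.78%) and 157810 higher (1.77%) in females. Windows differing by at least 20 points numbered 230 lower and 294 higher in females. After subtraction of each group's mitochondrial level they numbered 303 lower and 246 higher, and at a threshold of 10 points without subtraction 11911 lower and 7680 higher, so which direction held more depended on both settings. Unchanged simulated windows of chromosome 19 had the male levels in both groups and the minimum of 8 reads per CpG. Their rate, scaled to all windows, would be 342 in both directions for counting error alone. With at least 10 CpGs the measured counts were 20 and 49. After the same subtraction the difference of the means was -1.41 points. Windows 4 kb from those called lower in females had a median difference of -1.20 points, and those 4 kb from windows called higher -0.235, against -0.869 over all windows.

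The largest sex differences over windows were on the X (61814001 to 61816000, 6 CpGs), at 48.6% (SD 6.49) in females and 6.25% (SD 10.46) in males, and on chromosome 8 (50158001 to 50160000), at 82.5% and 40.4%. In the other direction a window on chromosome 11 (21128001 to 21130000, 5 CpGs) read 0% in females and 36.4% (SD 16.4) in males. On the X (8214001 to 8216000, 5 CpGs) the levels were 16.2% in females and 50.8% in males. These are the extremes of 597396 windows and have no replicate value behind them.

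The share of methylation left differed between classes of CpG density. On autosomes, CpGs with 0 to 2 neighbours went from 18.9% at E10.5 (SD over autosomes 0.416) to 8.54% at E11.5, and those with 3 to 7 neighbours from 19.5% to 8.89%. At E11.5 these classes stood at 45.1% and 45.6% of their E10.5 level. At E12.5 they stood at 32.1% and 32.4% of it in females, and at 37.1% and 36.4% in males. CpGs with 8 to 15 neighbours went from 17.5% (SD 2.57) to 10.7% (SD 1.94), or 61.1% of the E10.5 level, and stood at 49.98% of it in E12.5 females and 48.7% in males. The classes were not matched on their levels at E10.5. At that stage 9.49% of CpGs with 8 to 15 neighbours were at 50% or more, against 1.89% of those with 0 to 2. These shares therefore do not separate density from the level at the start. The densest class, with a density typical of CpG islands, read 3.50% at E10.5, 3.34% at E11.5, 3.59% in E12.5 females and 3.07% in E12.5 males. On the X, CpGs with 8 to 15 neighbours read 32.6%, 23.0%, 19.5% and 18.1% in the same order of groups. The X exceeded the autosomes in every density class and group, by 0.853 points at the least (0 to 2 neighbours, E12.5 males) and 15.1 points at the most (8 to 15 neighbours, E10.5).

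**Figure D3:**
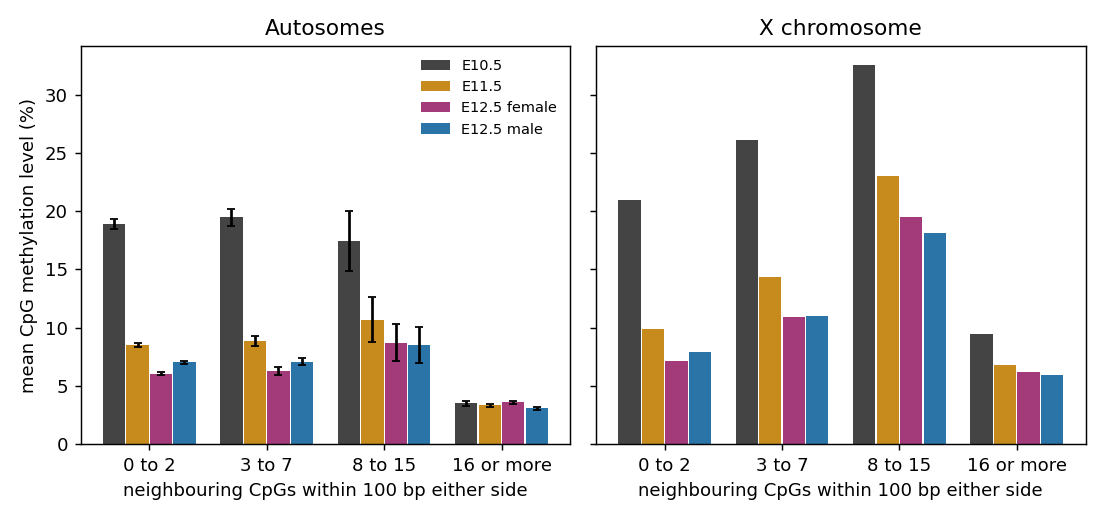
Mean CpG methylation level (%, y axis) by the number of neighbouring CpGs within 100 bp on either side (x axis), for autosomes (left) and the X chromosome (right), per group. Error bars are the SD over the 19 autosomes and do not exist for the X; on the autosomes the densest class stays between 3.07% and 3.59%, and the class of 8 to 15 neighbours on the X reads 32.6% at E10.5.

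The last question was which sequence kept methylation at E12.5. A level of 20% or more was found in 17515 windows in females and 17152 in males, and 13875 windows were in both lists. These residual windows made up 2.32% of those measured (95% Wilson interval 2.28% to 2.36%, which treats windows as independent). Independent lists of those sizes would share 503. Of the residual windows, 98.6% were also at 20% or more at E11.5, and 1286 were at 50% or more in both sexes. Their medians were 54.5% at E10.5, 41.7% at E11.5, 34.7% in E12.5 females and 33.8% in E12.5 males. In all other windows the medians were 18.1%, 7.62%, 5.18% and 6.19%.

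Residual windows were unevenly placed. They made up 12.9% of X windows (734 of 5677) and 2.22% of autosomal windows, from 1.19% on chromosome 11 to 3.37% on chromosome 3. The X windows rest on 104693 common X CpGs, where the female group held 573288 and the E10.5 group 199316. The X share over other X CpGs was not computed. By density residual windows made up 0.513% of windows averaging below 3 neighbours per CpG, 4.39% of those from 3 up to 8, 18.5% of those from 8 up to 16, and 0.388% of the densest. Where a tested window lay directly beside a residual one, 56.4% of 8942 residual windows had a residual neighbour.

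The highest E12.5 level in a window with at least 10 CpGs among the 10 named highest windows was on the X (158618001 to 158620000, 10 CpGs), at 82.2% (SD 6.37) at E10.5, 68.4% at E11.5, 80.04% (SD 10.9) in females and 83.9% (SD 10.7) in males. A window on chromosome 13 (118862001 to 118864000, 14 CpGs) read 76.9%, 77.6%, 78.8% and 77.99% in the same order. On chromosome 8 (93946001 to 93948000, 9 CpGs) the levels were 67.1%, 71.4%, 83.4% and 77.8%. On chromosome 2 they were 96.4%, 84.6%, 81.8% and 91.7% in one window (123348001 to 123350000, 5 CpGs) and 86.0%, 98.0%, 86.7% and 86.7% in another (6694001 to 6696000, 5 CpGs). No test was applied to these levels.

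**Figure D4:**
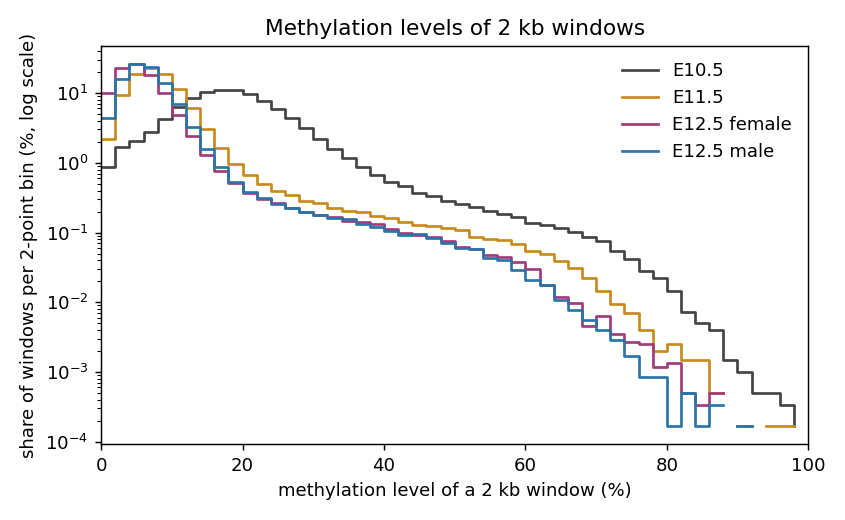
Share of 2 kb windows (%, log scale, y axis) by methylation level in bins of 2 percentage points (%, x axis), one line per group, over 597396 windows. The main peak moves from a median of 18.3% at E10.5 to 7.72% at E11.5, 5.27% in E12.5 females and 6.28% in E12.5 males. At E10.5 a level of 20% lies within the main peak, with 41.1% of windows at or above it. A tail of windows at 20% or more remains at E11.5 and in both E12.5 groups.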

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

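The tests of mitochondrial levels, of separately deposited values, of X CpGs chosen by coverage and of X levels in males were chosen after the results were seen. The tests of the ratio between window classes and of matched X windows were written down before their outcome was known.

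Mean levels at E12.5 differed between the sexes: females minus males was -0.687 points, with the same sign on 19 of 19 autosomes. The E11.5 titles name no sex, so no loss could be measured from a level of the same sex. A lower bisulphite background in the female libraries would lower unmethylated sequence too, but mitochondrial CpGs read 0.721 points higher in females (SE 0.0718). A small share of methylated somatic cells in the male sort may account for the lower female level. In CpG-poor autosomal windows the male excess was 0.964 points at 10% to 20% at E10.5 and 0.682 (SD over autosomes 0.388) at 40% to 60%. Such a share would give this ratio of 0.707, but so would a roughly constant male excess of any other source, so the ratio does not single out somatic cells. Over windows of every density, male minus female was 0.943 points at 10% to 20% but -0.310 at 40% to 60% and -1.25 at 60% to 80%, where a somatic share alone would not put males lower. A difference between the libraries rather than between the sexes cannot be told apart from either, because only 1 value per CpG and sex was deposited, and a difference of timing or sex in loss of methylation stays open and untested.

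The X chromosome stood above the autosomes at E12.5, by 3.81 points in females and 3.28 in males over the common CpGs. Choice of X CpGs by their coverage at E10.5 cannot be the whole cause, since over every CpG of each group the excess was 3.27 points in females and 2.41 in males, though both are lower. Methylation of an inactive X in females cannot be the whole cause either, since males, which have a single X, showed 3.28 points over the common CpGs and 2.41 over every CpG. X windows matched to autosomal windows on CpG density and E10.5 level exceeded them by 0.391 points, against 4.57 unmatched, and 12.3% of both were residual, so the E12.5 excess may be carried by windows that were dense in CpGs and highly methylated at E10.5 already. The remaining 0.391 points lie outside the range of single autosomes matched in the same way (-0.115 to 0.133), and why X windows started higher was not tested.

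The female E12.5 group held 231 Y CpGs, where none is expected, of which 151 were also among the 5225 of the male group and 62 were in all 4 groups and so among the 8916125 common CpGs.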

How the results depend on the processing

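Subtraction of the mitochondrial level, CpGs outside residual windows and CpGs of the E11.5 and E12.5 groups alone were alternatives chosen after seeing the data. No paired analysis was possible because each group's libraries were deposited as one set of levels, and for the same reason no library could be left out. All 4 differences of mean level kept their direction, on 19 of 19 autosomes, under every alternative run (every CpG, autosomes only, mitochondrial subtraction, outside residual windows and, for E12.5, without requiring E10.5). Their p stayed at the smallest the test can give and so says nothing of stability, and the sex difference went from -0.687 to -1.41 points with mitochondrial subtraction. The differences ranged from -9.86 to -9.17 points for E11.5 minus E10.5, from -3.06 to -2.20 points for E12.5 female minus E11.5, from -1.76 to -1.48 points for E12.5 male minus E11.5, and from -1.41 to -0.693 points for E12.5 female minus E12.5 male. Over every CpG of each group the means were 9.41%, 6.88% and 7.65% at E11.5, in E12.5 females and in E12.5 males. Minus the mitochondrial level they were 14.6, 4.77, 1.71 and 3.12 points, in order of group. Counts past a threshold changed with it, by construction. They follow as lower/higher for E11.5 minus E10.5, E12.5 female minus E11.5, E12.5 male minus E11.5 and E12.5 female minus male. At 10 percentage points CpGs numbered 3883467/511906, 1576973/727570, 1371356/754960 and 1097247/884446, and windows 304413/873, 34515/3541, 26404/3989 and 11911/7680. At 30 percentage points CpGs numbered 785127/12373, 63612/18958, 59691/13765 and 24547/29946, and windows 5962/3, 124/6, 143/3 and 7/14. With 5 kb windows, counts were 23857/11, 576/17, 728/25 and 93/116. With 1 kb windows they were 81458/65, 2748/206, 2796/151 and 436/611. With at least 10 CpGs, where 317892 windows were tested, they were 22769/0, 448/2, 607/2 and 20/49. Residual windows numbered 7528 at 30%, 36083 at 10% and 8697 with at least 10 CpGs, the last being 2.74% of those tested. With density taken within 250 bp and the classes scaled to it, 24 of 32 class levels moved by more than the SD over autosomes, and the cause was not tested. In order of group, the densest class read 2.97, 3.02, 3.37 and 2.84% on autosomes and 6.63, 4.87, 4.79 and 4.34% on the X. The class scaled up from 8 to 15 neighbours read 12.02 and 8.54% on autosomes at E10.5 and E11.5, and 27.7, 20.3, 17.4 and 16.2% on the X. The class scaled up from 3 to 7 neighbours read 9.38, 6.77 and 7.43% on autosomes from E11.5 on, and 30.2, 18.4, 14.5 and 14.2% on the X. The sparsest class read 21.5, 10.2 and 7.36% on the X at E10.5, at E11.5 and in E12.5 females. Coverage minimums, coverage weighting, a coverage maximum and thinning were not run, since read counts were not used here, and the unknown depth limits every statement on a single CpG or window.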

Other observations

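CpG-rich sequence that was methylated at E10.5 was left at unequal levels at E12.5. Of 12978 autosomal windows averaging at least 12 neighbouring CpGs, 782 (6.03%) were at 20% or more at E10.5. Their medians were 57.5% at E10.5, 43.7% at E11.5, 35.1% in E12.5 females and 32.9% in E12.5 males. By E12.5, 121 (15.5%) were below 10% in both sexes and 450 (57.5%) were residual. On the X, 93 of 373 such windows (24.9%) were at 20% or more at E10.5, of which 11 (11.8%) were below 10% in both sexes at E12.5 and 55 (59.1%) were residual.

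Residual windows were concentrated in some 1 Mb stretches. Over 2184 stretches with at least 50 windows the median share of residual windows was 1.52%. It reached 39.7% (23 of 58) on chromosome 17 (39000001 to 40000000), 38.3% (31 of 81) on chromosome 7 (32000001 to 33000000), 37.9% (22 of 58) on chromosome 19 (13000001 to 14000000) and 37.5% (30 of 80) on chromosome 9 (12000001 to 13000000). These stretches were chosen after their values were seen.

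The test of overlap between the sexes was chosen after the lists were seen, and that of empty flanking sequence before its result was known. The female and male lists shared 27.6 times as many windows as independent lists would, so the lists were not independent. Of the female list 79.2% was in the male list, and of the male list 80.9% was in the female list. Any difference in level between windows that both sexes share would raise this overlap. The test therefore cannot say how many residual windows passed the threshold through sampling noise over few CpGs. A hypothesis is that part of the residual windows border repeated sequence to which reads cannot be assigned. Residual windows lay beside a stretch of at least 4 kb with no CpG in any group in 1.91% of cases (263 of 13779, 95% Wilson interval 1.69% to 2.15%), against 0.214% of windows matched on CpG count and chromosome, a ratio of 8.92. This is consistent with the hypothesis for a small part of the residual windows and leaves the others open, and neither the repeats themselves nor reads placed at a wrong copy were tested.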
